A study of Mus musculus with 14 samples.

How the data were processed

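Whole blood of 14 mice was profiled, 1 array each per the labels: 4 control, 5 sublethal and 5 lethal, with globin RNA depleted before labelling. The deposited sample values are log2 of bead signals summarised with BeadStudio 3.0, without normalization between arrays and without detection p-values. This was checked on the files: 99.88% of the antilogs had a single decimal place, within a tolerance of 0.05 of the last digit, as that program writes signals. The value table of the series, also deposited on a log2 scale, holds other numbers. Its differences between arrays equal log2 of signal minus an array background, floored at 5, minus the 75th percentile of the array, with a largest residual of 0.03. A baseline of unknown definition was then subtracted from each probe. The authors' notes do not state these steps, and they were recovered from the values. The floor holds 42.0% to 56.3% of the probes of an array, and the most frequent value of an array in that table runs from 0.845 in sublethal replicate 1 to -0.63 in lethal replicate 5.

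The lists, comparisons, tests, thresholds and most alternatives were fixed before the data were examined. The plan named a route for signals that were not normalized and another for log values, and the deposited values were both. The route for signals was taken: antilog, normexp background correction with an offset of 16, quantile normalization and log2, in limma 3.58.1 under R 4.3.3. The values used as deposited are given as an alternative. Without detection p-values, probes with a mean log2 value above the 30th percentile were kept. Of 24613 probes, 20984 had exactly 1 gene symbol in the probe table, 1 had several and 3628 had none. The gene identifiers of 20968 matched the gene table, and 0 symbols needed an update. The brightest probe stood for each gene, which left 11913 of 15967 genes. No genome build is given with the arrays, so no coordinates are reported.

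The background of each array was recovered from the value table, and a probe counted as above background when its signal passed that level by more than 3 SD of the background. For a gene above background on 0 arrays of a group, a fold is given as a lower bound, computed with the dim values raised to the lowest value of a probe above background on the same array. Sublethal replicates 4 and 5 differed far less than any other pair of arrays, so they were averaged and counted as 1 sample. The files do not say whether the pair was 1 mouse or 1 RNA measured again. The plan named a fit on all 14 arrays, and the averaging was chosen after the data were seen.

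A mean per group was fitted over the 13 samples with lmFit, and the 3 contrasts were tested with eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 30 fixed gene lists, each with at least 5 measured genes, were tested with camera at a preset correlation of 0.01, adjusted over all lists of a comparison. Beside it stand camera with an estimated correlation, fry and camera on ranks. A list score is the mean over members of the log2 value minus the control mean. The genes named in each comparison are the 8 largest rises and the 8 largest falls past the threshold, and up to 2 called members of each list described. Where fewer than 5 genes passed, they are the 5 with the smallest p. Sirt3 and the liver genes lie outside this rule and were chosen after their values were seen. For the overlap of both infections, unchanged groups were simulated 100 times from the residuals of all groups pooled, and the 4 controls were divided in 6 ways.

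Replicate numbers were checked for pairing: the 12 pairs of samples with the same number correlated at -0.132 to 0.214 after group means were removed, 3 of them above 0.1, and 1 of 13 samples correlated best with its own number. The numbers were therefore not treated as pairs. The files name no slide or scan batch. The steps were tested on simulated data with known changes and independent noise: of the changed genes at 2-fold, 71.4%, 71.4% and 59.4% were recovered for lethal minus control, sublethal minus control and lethal minus sublethal, with 8, 4 and 4 unchanged genes called. A list shifted by 1.5-fold was called each time, and 0 of the 30 other lists were.

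Alternatives changed the background step, scaling, filter, probe choice, source of values, fit, weights, thresholds, list test and samples. Added after seeing the data were the deposited values, filters on the background level, and fits with or within levels of the H2-D1 probe. So was a fit without the 3 samples with the highest hepatocyte scores. The planned fit on all 14 arrays is given as an alternative. A list of 34 hepatocyte genes was written after other liver transcripts were noticed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for reading files and drawing.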

Results

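Gene expression was measured on Illumina bead arrays in the whole blood of young female BALB/c mice, an inbred strain. The labels place 4 arrays in a control group injected with PBS, 5 in a sublethal group and 5 in a lethal group. Infected mice received the yeast Candida tropicalis into the tail vein. The injected volume was 100 µl of PBS in controls and 200 µl in both infected groups, so volume differs with infection in each comparison with controls. The inoculum was 10 to the power of 5 colony-forming units in the sublethal group and 10 to the power of 7 in the lethal group. The labels give day 7 as the endpoint.

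Each array held 24613 probes, and 11913 genes with 1 probe each were compared. Signal stood above the background level on 27.8% to 29.8% of the probes of the control arrays. That share was 22.4% to 35.6% on sublethal arrays and 35.0% to 39.0% on lethal arrays. The number of arrays limits the precision of every value. Sublethal replicates 4 and 5 were nearly the same array: over 1052 bright probes their log2 values differed with an SD of 0.11, against 0.29 or more in the other 90 pairs of arrays. Across 72 genes with a second probe, the differences of both probes correlated at r = 0.0897 in this pair and at 0.439 to 0.959 in the others, where genes are not independent replicates. The pair was averaged and counted as 1 sample, which left 13 samples and n = 4 in the sublethal group.

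On the first principal component, which held 44.9% of the variance, the controls lay between -27.1 and -24.9 and the lethal samples between 10.05 and 31.73. The sublethal samples ran from -46.6 in replicate 1 to 26.2 in replicate 4-5.

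**Figure D1:**
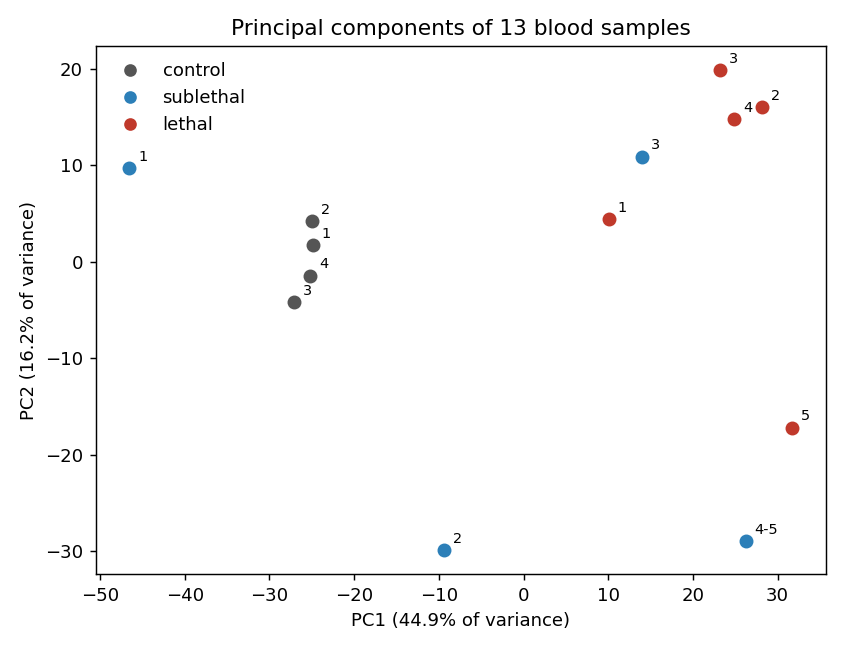
Principal components of the 13 blood samples, with the first component on the x axis (44.9% of the variance) and the second on the y axis (16.2%). Each point is a sample with its replicate number, and lethal samples lie between 10.05 and 31.73 on the x axis while controls lie between -27.1 and -24.9.

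The comparison of lethal with control mice asked how blood transcripts differ after an inoculum that kills. By camera with a preset correlation, fixed lists of neutrophil and monocyte genes were higher in lethal blood and those of T cell, B cell and erythroid genes lower after quantile normalization, with 7 to 14 members of each passing in limma. Each of these calls was lost with an estimated correlation (adjusted p = 0.197 for the former and 0.381 for the latter). Fry, which asks whether members move on balance, called 15 lists in this comparison, these among them. Its adjusted p was 0.00963 for mature neutrophil, 0.0105 for monocyte, 0.0235 for T cell and 0.0408 for B cell and erythroid genes. It did not call the platelet, interferon gamma, oxidative phosphorylation and cell cycle lists. The largest rise was that of Saa3, an acute-phase serum amyloid, at 3.52 ± 0.89 on the log2 scale (fitted difference ± SE, n = 5 and 4), or 11.5-fold. Wfdc21, a secreted protein made by neutrophils, rose 10.3-fold, and Lcn2, which binds the siderophores that carry iron to microbes, rose 9.52-fold. Ifitm6 and the chitinase-like Chil1 rose 7.71-fold and 6.60-fold, and Chil4 was at least 4.30-fold higher on its brightest probe and differed by -0.22 on its other probe. Of 11913 genes, 1131 rose and 1332 fell in limma at an adjusted p under 0.05, with 280 rises and 144 falls of at least 2-fold. The groups did not overlap for 3497 genes, or 29.4%, where chance gives 1.59%.

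The fixed list of mature neutrophil genes had a score of 1.13 ± 0.17 (mean log2 difference from controls ± SD, n = 5), and each of the 5 lethal samples lay above all controls. Of its 22 measured members 14 rose and 0 fell; adjusted over the list alone, 15 rose and 1 fell. Retnlg, a resistin-like protein of neutrophils, rose by 3.14 ± 0.53 (adjusted p = 0.00802), and Fpr2, a formyl peptide receptor, by 2.30 ± 0.45. The alarmins S100a8 and S100a9 rose 4.55-fold and 3.62-fold. Of 18 measured members of the granule precursor list 8 rose and 0 fell (10 and 1 adjusted over the list alone). Ngp, a neutrophil granule protein, was at least 4.54-fold higher in lethal blood, since it was above background on 0 of 4 control arrays; its call held in 17 of 29 alternatives. In the monocyte list 9 of 16 members rose and 0 fell (12 and 0 adjusted over the list alone), with Adgre1, the macrophage marker F4/80, at 2.41 ± 0.70 and Ms4a6d at 2.20 ± 0.56. These lists passed camera at adjusted p = 9.3e-08, 0.000241 and 1.0e-06. Each had an adjusted p = 0.197 with an estimated correlation, and the granule list also lost its call under median scaling (adjusted p = 0.0536, and 1.3e-05 to 0.0941 over 29 alternatives). Under that scaling its members still stood 1.23 above the other genes. Lethal replicate 1, whose H2-D1 probe lay at the control level, had scores of 1.10 for mature neutrophils and 0.86 for monocytes.

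**Figure D2:**
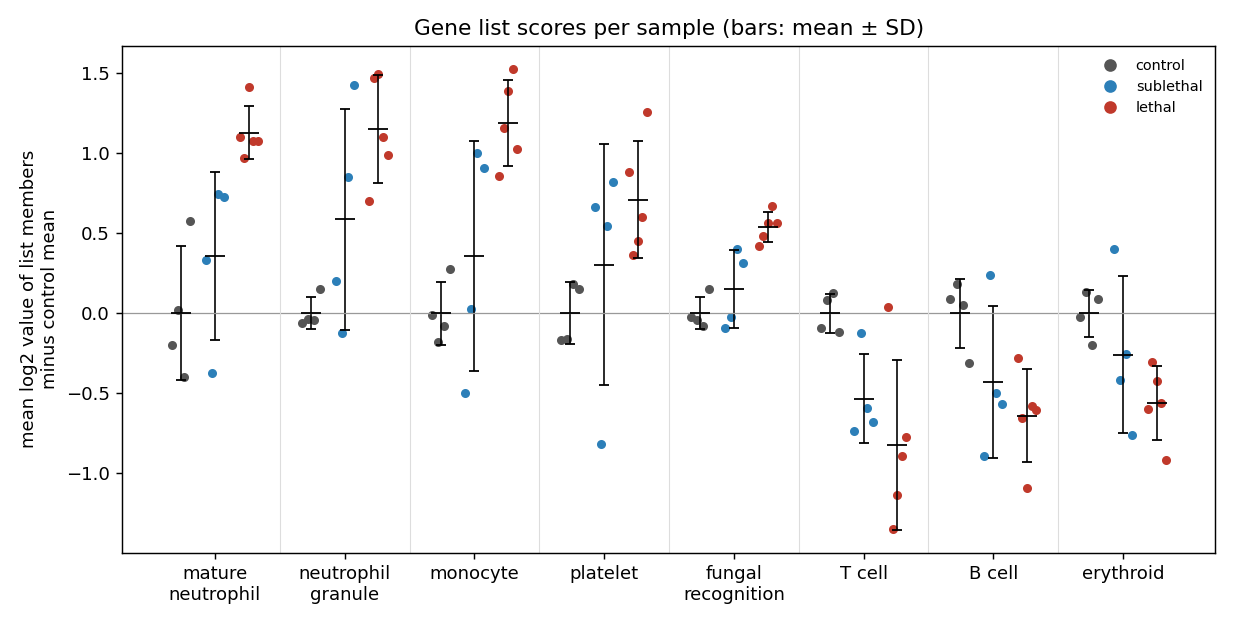
Scores of 8 fixed gene lists (y axis, mean log2 value of the members minus the control mean) in control, sublethal and lethal samples, as points with bars for mean ± SD. Lethal scores for mature neutrophil genes lie between 0.97 and 1.41, and for T cell genes between -1.35 and 0.04.

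Genes of fungal recognition rose in 9 of 30 members and fell in 1 (13 and 3 adjusted over the list alone; camera adjusted p = 7.0e-05). With an estimated correlation the adjusted p was 0.156, the lowest of any list in this comparison. Itgb2, the shared chain of the leukocyte integrins, rose by 1.82 ± 0.32, and Lgals3, a lectin that binds yeast mannans, by 1.64 ± 0.41. In the list of phagocyte oxidase and granule killing 9 of 27 rose and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000241, and adjusted p = 0.197 with an estimated correlation). Among inflammatory cytokine genes 8 of 28 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.000476, and adjusted p = 0.197 with an estimated correlation). Cxcl2, a chemokine that draws neutrophils, was at least 2.01-fold higher and Il6 at least 1.29-fold higher, each above background on 0 control arrays. The anti-inflammatory list had 6 of 19 up and 1 down (7 and 2 adjusted over the list alone; camera adjusted p = 0.000241, and adjusted p = 0.197 with an estimated correlation), among them Socs3, a brake on cytokine signalling, which rose 2.68-fold. Lethal replicate 1 scored 0.33 on the cytokine list and 0.38 on the anti-inflammatory list, the lowest of the 5 lethal samples on each.

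Type I interferon genes rose in 8 of 23 members and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.197 with an estimated correlation). Trim30a was at least 1.73-fold higher, while Irf7, a transcription factor that drives interferon genes, fell by 1.75 ± 0.53. The call on Irf7 ended under median scaling (adjusted p = 0.234, and 0.00159 to 0.61 over 30 alternatives). In the interferon gamma list 7 of 22 rose and 1 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0214, and adjusted p = 0.381 with an estimated correlation). Gbp3, a guanylate-binding protein, rose by 1.32 ± 0.28 and Psmb9, an immunoproteasome subunit, was higher in 5 of 5 lethal samples than in any control (adjusted p = 0.0246). Without normalization both interferon lists and the inflammatory cytokine list lost their calls. The members of the type I, interferon gamma and cytokine lists still stood 0.45, 0.72 and 0.50 above the other genes there. Psmb9, above background on 1 of 4 control arrays, ran opposite to the H2-D1 probe: it was at 6.67 in lethal replicate 1 and between 8.52 and 9.04 in the other 4 lethal samples.

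Complement and coagulation genes rose in 7 of 19 members and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00292, and adjusted p = 0.197 with an estimated correlation). The list's call held in 26 of 30 alternatives (adjusted p from 0.000387 to 0.685). It ended without normalization, where the members stood 0.60 above the other genes. Lethal replicate 1 scored 0.16, within the control range. Cfb, complement factor B, was above background on 5 of 5 lethal and 1 of 4 control arrays (adjusted p = 0.0166), and Cd59a, an inhibitor of the membrane attack complex, fell by 2.27 ± 0.73. The call on Cd59a held in 14 of 30 alternatives (adjusted p from 0.00102 to 0.786), and the difference was -1.07 under median scaling and -0.74 without normalization. A list of hepatocyte genes scored 1.95 in lethal replicate 5, 1.71 and 2.58 in sublethal replicates 2 and 4-5, and between -0.19 and 0.19 in the other 10 samples. Some liver transcripts differed among those 10 too: Apoa2 was at 8.71 and 9.66 in control replicates 3 and 4 and at 5.85 and 5.73 in control replicates 1 and 2. Glycolysis and hypoxia genes rose in 11 of 23 members and fell in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.197 with an estimated correlation), with Gapdh at 1.36 ± 0.26 and Pkm at 1.27 ± 0.30, both glycolytic enzymes. The platelet list had a camera adjusted p = 1.1e-05, and an adjusted p = 0.381 with an estimated correlation, though 4 of 28 members rose and 0 fell, the same numbers as adjusted over the list alone. Thbs1, a thrombospondin of platelet granules, was at least 1.71-fold higher. Gp1bb, part of the platelet receptor for von Willebrand factor, rose by 1.83 ± 0.52 on its brightest probe and differed by -0.26 on its other probe.

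**Figure D3:**
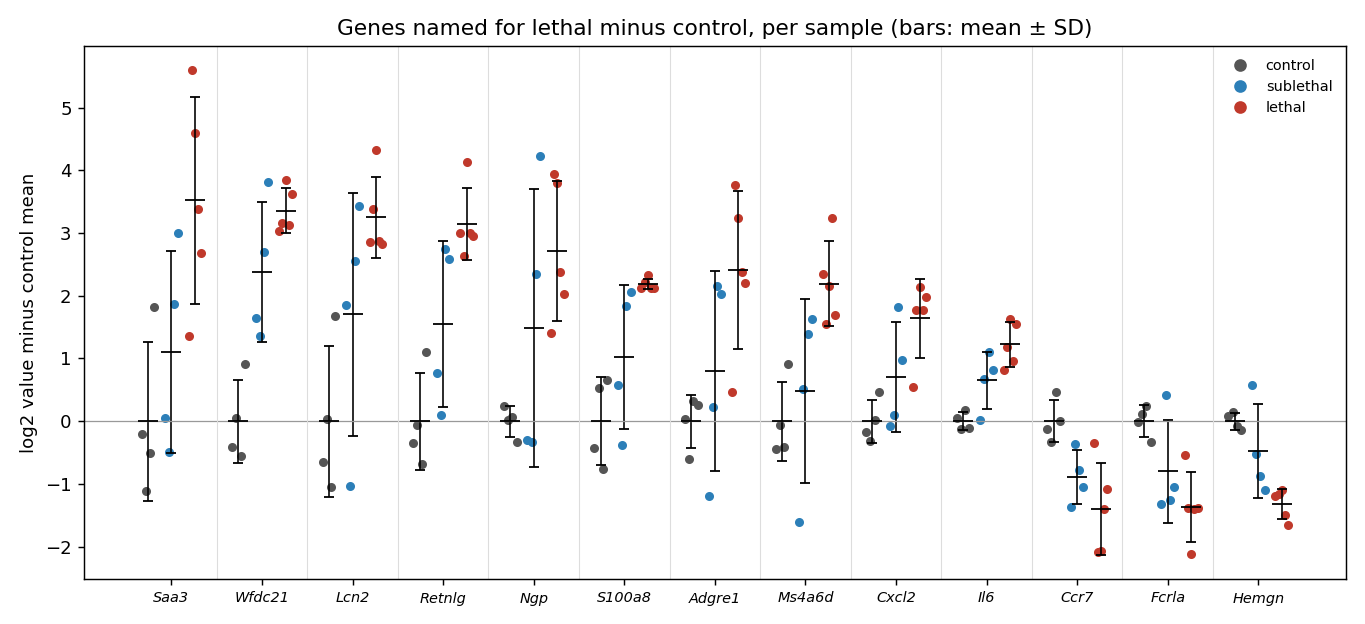
Log2 values minus the control mean (y axis) of 13 genes named for lethal against control blood, with a point per sample and bars for mean ± SD. Lethal samples lie above all controls for 9 of the 10 genes that rose, Saa3 being the exception, and below all controls for Ccr7, Fcrla and Hemgn, whose falls depend on the normalization.

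The T cell list had a score of -0.82 ± 0.53 (SD, n = 5). Of its 27 measured members 14 fell and 0 rose (18 and 0 adjusted over the list alone; camera adjusted p = 4.3e-06, and adjusted p = 0.381 with an estimated correlation). Ccr7, a homing receptor of naive T cells, fell by 1.39 ± 0.32, and Cd8b1, a chain of the CD8 coreceptor, fell by 2.65 ± 0.69 on its brightest probe, while its other probe differed by 0.51. Of 24 measured B cell genes 10 fell and 0 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.000512, and adjusted p = 0.381 with an estimated correlation), among them Fcer2a, the low-affinity IgE receptor, and Fcrla, which fell by 1.45 ± 0.33 and 1.37 ± 0.35. Of 27 erythroid genes 7 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.000476, and adjusted p = 0.381 with an estimated correlation), with Hemgn, a nuclear protein of erythroid cells, at -1.32 ± 0.26 and Ube2l6, a conjugating enzyme for ISG15, at -1.92 ± 0.50. The calls on Cd8b1 and Fcer2a ended under median scaling, where they differed by -1.62 and -0.77. None of the T cell, B cell and erythroid lists was called under median scaling (adjusted p = 0.127, 0.611 and 0.42), 75th percentile centring (0.443, 0.98 and 0.72) or in the value table of the series (0.0837, 0.432 and 0.176). Over 30 alternatives the T cell list had an adjusted p from 5.5e-12 to 0.443, the B cell list from 4.1e-05 to 0.98 and the erythroid list from 3.8e-05 to 0.72. Without normalization Ccr7, Fcrla and Hemgn differed by 0.16, 0.12 and 0.02, the opposite direction. Lethal replicate 1, with H2-D1 at the control level, had a T cell score of 0.04, and the other 4 lethal samples scored from -1.35 to -0.77.

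Another 4 lists were called upward with 1 to 6 members that rose. Stress protein genes rose in 5 of 19 members and fell in 0 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0214). Glucocorticoid response genes rose in 5 of 21 and fell in 1 (7 and 4 adjusted over the list alone; camera adjusted p = 0.0189). Both had an adjusted p = 0.197 with an estimated correlation, and the glucocorticoid call held in 25 of 30 alternatives (adjusted p from 0.00189 to 0.634). Cell cycle genes rose in 6 of 31 and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0295, and adjusted p = 0.613 with an estimated correlation). Their scores were 0.73 and 0.70 in lethal replicates 2 and 3 and between -0.11 and 0.07 in the other 3 lethal samples, and the call held in 16 of 30 alternatives (adjusted p from 0.00214 to 0.934), not under median scaling. The oxidative phosphorylation list had a camera adjusted p = 0.0401 and a positive mean of 0.18, yet 1 of its 33 members rose and 4 fell, also adjusted over the list alone. Its adjusted p was 0.594 with an estimated correlation, and the call held in 22 of 30 alternatives.

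Among the genes with the largest fitted falls were several of the major histocompatibility complex. H2-D1, a class I gene, fell by 4.83 ± 1.59 (adjusted p = 0.0463), but it was above background on 2 of 5 lethal arrays, so the size of its fall is not resolved. Its call held in 12 of 27 alternatives (adjusted p from 0.00437 to 0.0964). It ended, for example, under median scaling (difference -4.19) and without the 3 samples with the highest hepatocyte scores (-4.44). The class II genes H2-Ea and H2-Eb1 fell by 3.89 ± 0.99 and 3.28 ± 0.80, while H2-K1, another class I gene, was at least 3.505-fold higher on its brightest probe and differed by 0.38 on its other probe. The call on H2-Eb1 held in 26 of 30 alternatives and ended under median scaling (difference -2.36) and without normalization (-1.82). H2-Q6 fell by 2.63 ± 0.72, with a call that held in 16 of 30 alternatives, Cd59b, an inhibitor of complement, fell by 3.15 ± 0.80, and Ybx3, a nucleic acid binding protein, fell by 2.52 ± 0.56. Values differed widely within groups. H2-D1 was between 5.19 and 5.81 in lethal replicates 2 to 5, at 5.83 and 4.98 in sublethal replicates 3 and 4-5, and between 11.5 and 12.2 in the other 7 samples. The other probes did not all share that division: H2-Ea was at 7.00 and 9.55, and Ybx3 at 12.08 and 9.44, in sublethal replicates 3 and 4-5. Sirt3, a mitochondrial deacetylase singled out after its values were seen, went the other way. It lay between 12.60 and 14.02 in the same 6 samples and between 6.22 and 7.10 in the other 7 (lethal minus control adjusted p = 0.0547). The class II list (5 of 18 fell, 0 rose; 5 and 1 adjusted over the list alone) and the class I list (4 of 16 rose, 2 fell; 6 and 2 adjusted over the list alone) were not called, at camera adjusted p = 0.238 and 0.123.

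Among called genes 45.9% rose, against 87.7% of 4402 under median scaling, 22.6% of 8164 under 75th percentile centring, 42.0% of 5691 in the value table and 99.9% of 8042 without normalization, where the median difference of all genes was -0.06, 0.09, -0.43, -0.24 and 0.33. The count was 1361, 1060 and 1091 without control replicates 1, 3 and 4, then 1461, 1444 and 1327 without lethal replicates 2, 4 and 5, and 4319 without sublethal replicate 1. With the H2-D1 value as a term in the fit, limma called 0 genes (1754 at an unadjusted p under 0.05). H2-D1 was low in lethal replicates 2 to 5 and in no control, so this term and the contrast largely overlap. That 0 therefore does not decide. All 40 named genes tested kept their direction, but each differed by less and lost its call. Wfdc21 differed by 2.49 with the term (3.36 without) and Cd59a by -0.29 (-2.27). These genes were named from the same data, so their direction is no separate evidence. Without the 3 samples with the highest hepatocyte scores limma called 1572 genes.

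**Figure D4:**
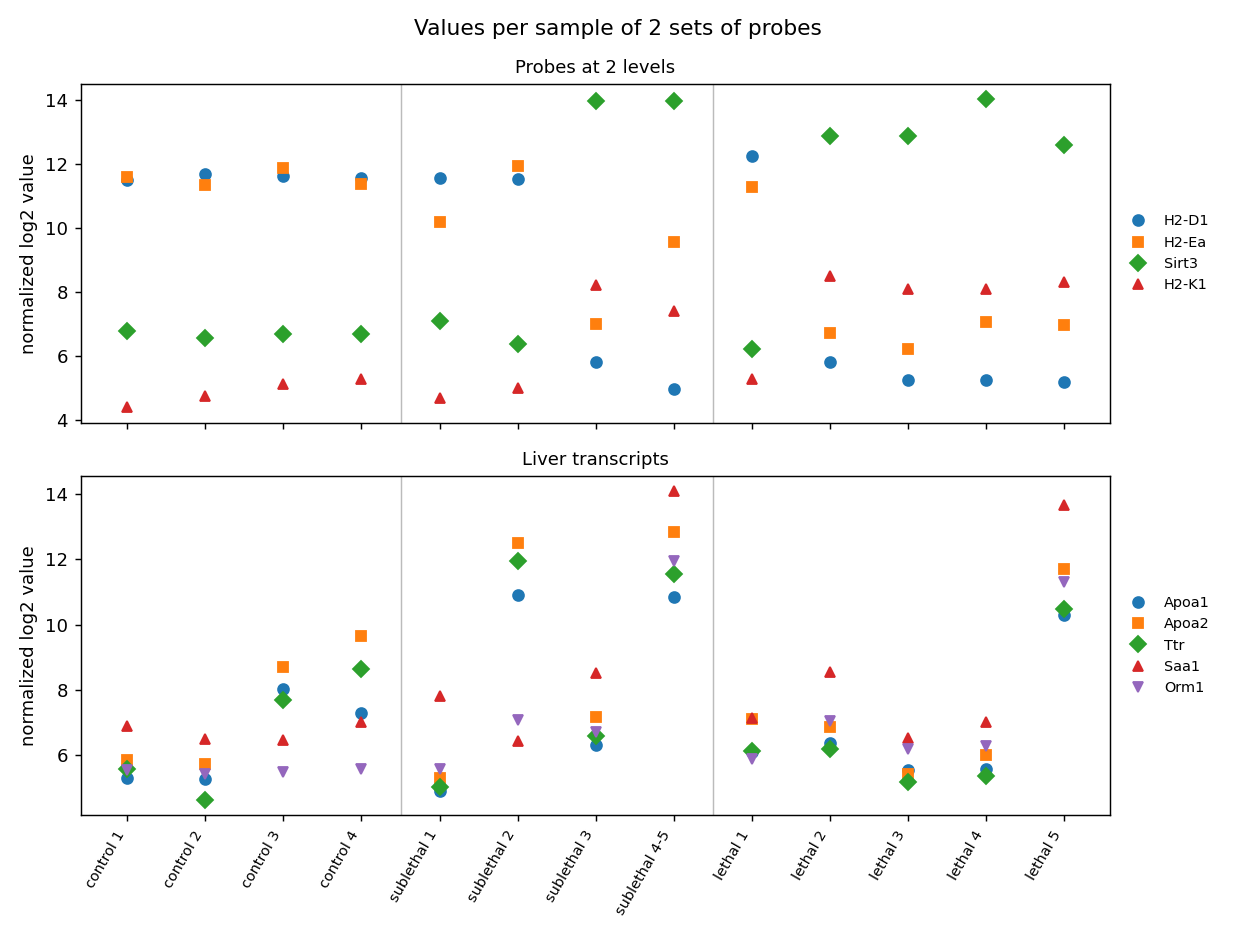
Normalized log2 values (y axis) of 4 probes at separate levels (upper panel) and of 5 liver transcripts (lower panel) in each of the 13 samples (x axis). H2-D1 lies between 4.98 and 5.83 in 6 infected samples and between 11.5 and 12.2 in the other 7, and Apoa2 lies between 11.7 and 12.8 in sublethal replicates 2 and 4-5 and lethal replicate 5.

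The comparison of sublethal with control mice asked what a dose that the mice survive leaves in the blood. T cell genes had a score of -0.53 ± 0.28 (SD, n = 4), below all controls in 4 of 4 samples. Replicate 2, at -0.126, lay barely below the lowest control, at -0.115. Granule precursor genes had a score of 0.59 ± 0.69, above all controls in 3 of 4. The mature neutrophil score was 0.36 ± 0.52, with 0.75 and 0.73 in replicates 3 and 4-5, the samples with low H2-D1, and 0.33 and -0.38 in replicates 1 and 2. Monocyte scores split the same way, at 1.00 and 0.91 against -0.50 and 0.03. No gene passed the threshold: limma called 0 genes, with 917 at an unadjusted p under 0.05 where chance gives 596, and the lowest adjusted p was 0.17. The groups did not overlap for 356 genes, or 2.99%, where chance gives 2.86%.

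The 5 genes with the smallest p were all lower in 4 of 4 sublethal samples than in any control, and each failed the correction. All 5 passed it when sublethal replicate 1 was left out, and with array weights. Krtcap3 differed by -0.60 ± 0.09, Zfp661 by -0.995 ± 0.16, Nsmce2, a SUMO ligase, by -0.60 ± 0.10 on its brightest probe (-0.03 and 0.04 on 2 other probes) and Setd1a, a histone methyltransferase, by -0.76 ± 0.13, each with an adjusted p = 0.17. Olfr145, an odorant receptor gene, differed by -0.68 ± 0.13 (adjusted p = 0.295).

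With the preset correlation camera called 10 lists upward and 3 downward. The lists for mature neutrophils, neutrophil granules, monocytes, platelets, interferon gamma, anti-inflammatory genes, fungal recognition, phagocyte killing, complement and glycolysis were upward, and those for B cells, T cells and erythroid cells downward. The B cell and erythroid lists were not called under median scaling or 75th percentile centring, nor the erythroid list in the value table. In the planned fit on all 14 arrays the interferon gamma list was not called (camera adjusted p = 0.0672). Its score lay above all controls in 1 of 4 sublethal samples and below all in 1. None of the 10 upward lists was called without normalization, where their members stood 0.16 to 0.52 above the other genes. The adjusted p of the 13 lists ran from 4.9e-08 for T cells to 0.0295 for the interferon gamma and fungal recognition lists. In these 13 lists 0 members passed over all genes tested, and adjusted over the list alone 1 B cell gene was lower. With an estimated correlation 0 lists were called, with an adjusted p from 0.457 to 0.539 in these 13 lists, and fry called 0. Hepatocyte scores were high in 2 of the 4 sublethal samples. The fit without the 3 samples with the highest scores kept sublethal replicates 1 and 3, so lost calls can come from fewer samples. It did not call the monocyte, anti-inflammatory, complement and erythroid lists, the last with a mean of 0.08 relative to the other genes. Leaving out sublethal replicate 1, which had signal above background on the fewest probes, gave 377 genes (140 higher, 237 lower), and without replicate 3 or replicate 4-5 camera called 6 lists, of which 6 and 4 were among the 13.

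The direct comparison of lethal with sublethal mice tested whether the doses differ in their effect. Apcdd1, a membrane protein that inhibits Wnt signalling, was the gene that passed. Its fitted difference was 1.32 ± 0.13 (n = 5 and 4, adjusted p = 0.00174), and it was at least 1.13-fold higher, above background on 5 of 5 lethal and 0 of 5 sublethal arrays. The next 4 genes by p each had an adjusted p = 0.165 and were higher in 5 of 5 lethal samples than in any sublethal one. Trim30a was at least 1.81-fold higher, and Knop1 was above background on 4 of 5 lethal and 0 of 5 sublethal arrays, with a difference of 0.0955 on its other probe. Bst1, a myeloid surface enzyme, differed by 0.93 ± 0.16 and Anxa2, a membrane-binding annexin, by 1.04 ± 0.19. There were 2350 genes at an unadjusted p under 0.05 where chance gives 596, and the groups did not overlap for 742 genes, or 6.23%, where chance gives 1.59%. Low H2-D1 marked lethal replicates 2 to 5 and sublethal replicates 3 and 4-5, so the doses differed in that division too. Within those 6 samples limma gave 646 genes at an unadjusted p under 0.05, near the chance count. Apcdd1 differed by 1.24 there and did not pass. That fit held fewer samples, so it does not tell whether the division or the lost samples lowered the count.

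Between the doses camera called 10 lists upward and 2 downward. Mature neutrophil genes differed by a mean of 0.77 and monocyte genes by 0.83 (adjusted p = 3.8e-08 and 1.8e-06). Granule precursor, platelet, type I interferon, inflammatory cytokine, anti-inflammatory, fungal recognition, phagocyte killing and glycolysis genes were also upward. T cell and erythroid genes were downward, by means of -0.29 and -0.30, and neither was called under median scaling, 75th percentile centring, in the value table or without normalization, where the sign turned (0.02 and 0.02 relative to the other genes). In these 12 lists 0 members passed over all genes tested. Adjusted over the list alone, 12 of 22 mature neutrophil genes and 8 of 16 monocyte genes were higher. With an estimated correlation 0 lists were called, with an adjusted p from 0.174 to 0.643 in these 12 lists, and fry called fungal recognition alone (adjusted p = 0.022). The fit without the 3 samples with the highest hepatocyte scores kept sublethal replicates 1 and 3, so lost calls can come from fewer samples. It did not call the T cell, platelet, phagocyte killing and glycolysis lists. Apcdd1 lost its call there too, with a difference of 1.24 against 1.32 as reported (adjusted p = 0.133, and 0.000241 to 0.268 over 30 alternatives). The count of genes was 1831 under median scaling, 5021 under 75th percentile centring, 18 in the value table and 3506 without normalization. It was 35, 5 and 8 without sublethal replicate 4-5, sublethal replicate 3 and lethal replicate 1.

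Both infections were compared with the same 4 controls, which alone makes their differences correlate. They shared 0 called genes upward and 0 downward, since limma called 0 in sublethal blood. Across genes, which are not independent replicates, their log2 differences correlated at r = 0.727, where groups simulated without change against shared controls gave a median of 0.574 and a range of -0.30 to 0.925. Their covariance was 0.0979, above the highest of 100 simulated values, 0.0898, and 0.0772 to 0.0893 when separate controls were used for each infection. The sign was the same for 76.0% of genes, within the simulated range of 38.8% to 89.1%, and for 63.9% to 69.1% with separate controls. With separate controls, where none are shared, the correlation was 0.489 to 0.620. Simulated controls drew on the residuals of all 13 samples and so varied more than the 4 real controls. Lying within a simulated range therefore does not decide. Without sublethal replicate 1 the infections shared 368 genes.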

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

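The tests of probe variants, of the neutrophil and monocyte rise, of a wrong label and of acute-phase genes were chosen after the result was seen. Those of strain and of liver RNA were written after the pattern was noticed and before their own result was seen. The test of other splits of the samples was written before its result was seen. Of 255 groups of samples tested for a sample far from the others, 22 held one, where chance gives 12.8, about 1 in 20 groups.

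H2-D1, H2-Ea, Sirt3 and other probes differed widely within the infected groups, and lethal replicate 1 lay far from the other 4 lethal samples in 11 genes. It was higher in H2-D1 (12.24, others 5.19 to 5.81), H2-Ea (11.285), H2-Eb1 (9.435), H2-Q6 (9.439), Ybx3 (11.775) and Ube2l6 (13.88), and lower in H2-K1 (5.27), Psmb9 (6.67), Cxcl2 (5.75), Chil4 (6.30) and Gapdh (11.33).

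A mouse of the control group under the label of lethal replicate 1 is argued against by its mature neutrophil score of 1.10, where the highest control had 0.57. Among what stays open for the levels themselves, mice of another strain, like C57BL/6, could not be tested with Ifi202b, which was above background on 0 arrays (r = 0.233 with H2-D1). Sequence variants under single probes could be one, since 31.0% of other probes of genes that follow H2-D1 did not follow it, against 18.4% for genes that follow S100a8 (Fisher's exact test, two-sided, p = 0.301). A response that goes with the neutrophil and monocyte rise is another, as 1 of 7 samples with both scores above all controls had H2-D1 at the control level, so these cannot be told apart.

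Liver transcripts were highest in sublethal replicates 2 and 4-5 and in lethal replicate 5, and some were raised in control replicates 3 and 4 (Apoa2 8.71 and 9.66, against 5.85 and 5.73 in the other controls). In a list of 34 hepatocyte genes, 29 were above background on at least 1 array, and their median difference between these 3 samples and the other 10 was 2.01 on the log2 scale, with all 29 higher and 23 separated. The controls had 2 of the 29 above background on all arrays, 0 are in the fixed lists, and the Alb probe was above background on 0 arrays. Hpx, a liver transcript not among the 29, is in the fixed iron and heme list. It was at 9.03, 13.25 and 12.67 in sublethal replicates 2 and 4-5 and lethal replicate 5. In the other samples Hpx lay between 5.11 and 8.02. Acute-phase genes induced in blood cells are argued against for sublethal replicate 2, where the mean of Saa1, Orm1 and Orm2 was 0.749 above controls and that of Apoa1, Apoa2 and Ttr 4.91 above. In sublethal replicate 4-5 and lethal replicate 5 these means were 6.38 and 4.41. Liver RNA could carry both sets, so the higher acute-phase mean does not tell where those genes were induced. The rise of Apoa1, Apoa2 and Ttr, with 23 of the 29 hepatocyte genes separated, argues against acute-phase induction as the whole source there too. Liver RNA in the blood samples may be the source in all 3.

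Other samples far from their group were Retnlg in lethal replicate 3 (13.605, others 12.09 to 12.46), Ybx3 in sublethal replicate 4-5 (9.441, others 12.08 to 12.62) and Fcrla in sublethal replicate 2 (9.60, others 7.86 to 8.13). Among controls, Itgb2 was low in replicate 3 (5.67) and Irf7 high in replicate 2 (9.38). The granule precursor score of control replicate 4 was 0.15 and the interferon gamma score of control replicate 2 was 0.23. The platelet score was -0.81 in sublethal replicate 2, the oxidative phosphorylation score -0.41 in sublethal replicate 1, and the iron and heme score 0.87 in sublethal replicate 4-5. Sublethal replicate 1 had signal above background on 22.4% of its probes, against 32.6% or more in the other sublethal arrays. Of 2435 probes without a single gene name, 477 were called between lethal and control blood, 203 higher and 274 lower.

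Chance can be excluded for the number of genes called between lethal and control blood: 1 of 100 splits of the 9 samples, the real one, gave 2463, and the highest other gave 550. For the 19 lists the splits do not decide, and chance is not excluded: 6 of the 100 gave as many, in whatever direction. The highest other, with 20, set all controls and lethal replicate 5 against the remaining lethal samples, nearly the real grouping turned round. Between sublethal and control blood limma called 0 genes (917 at an unadjusted p under 0.05), so all 35 splits gave as many. The highest other split, with sublethal replicate 1 among control replicates 1, 3 and 4, gave 362, which points to a structure of the samples. Chance cannot be excluded for the 13 lists (4 of 35 splits, highest other 16). Nor can it be excluded between lethal and sublethal blood, where 8 of 100 splits gave at least 1 gene (highest other 31) and 28 of 100 at least 12 lists (highest other 19). The splits with 16 lists, 31 genes and 19 lists each exchanged 1 sample of each group, as the grouping stands or turned round. They hold part of the real difference, so they do not decide either.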

How the results depend on the processing

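Chosen after seeing the data were the averaging of sublethal replicates 4 and 5, the values as deposited, the filters on the background level and the H2-D1 fits. The fit without the 3 samples with the highest hepatocyte scores, called liver samples here, was also chosen then. It keeps control replicates 3 and 4, where some liver transcripts were raised. The fit on all 14 arrays was the planned one. A filter on detection p and a slide or scan batch were not run, since the files hold neither. Array signal limits what can be seen, with 22.4% to 39.0% of probes above background. Of 1215 values of the 41 genes named for lethal minus control, 1013 kept direction and side of the threshold, 196 fell short and 6 reversed. For the lists called in that comparison it was 513 of 569, with 52 short. For lethal minus sublethal 128 of 151 gene values and 333 of 371 list values stayed, and for sublethal minus control 135 of 149 and 307 of 389. Where not stated, the cause was not tested.

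Genes called for lethal minus control, 2463 as reported, were 4402 under median scaling, 8164 under 75th percentile centring, 5691 in the value table and 8042 as deposited. They were 822 with a replicate block, 4283 with only the 2 groups compared, 4618 with array weights and 1313 above background on all arrays (3417 genes tested). They were 1572 without liver samples, 424 at 2-fold and 281 at an adjusted p under 0.01, the last 2 by construction. With H2-D1 as a term limma called 0 (1754 at an unadjusted p under 0.05), but that term largely overlaps with the contrast, so this 0 does not decide. Within the 7 samples with H2-D1 at the control level, lethal replicate 1 was the only lethal sample, so that fit gives effect sizes alone. There Retnlg differed by 2.99 (3.14 as reported) and S100a8 by 2.13 (2.19), but Saa3 by 1.35 (3.52), Adgre1 by 0.467 (2.41) and Cd8b1 by -0.0694 (-2.65). Leaving out 1 sample gave 1060 to 4319 genes.

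Genes called for sublethal minus control, 0 as reported, were 1 without background correction, 376 with array weights, 1 with all 14 arrays and 2 without liver samples, and 0 to 377 without 1 sample. Genes called in both infections were 1, 371, 1 and 2 in those settings and 0 to 368 without 1 sample. Genes called for lethal minus sublethal, 1 as reported, were 1831 under median scaling, 5021 under 75th percentile centring, 18 in the value table and 3506 as deposited. They were 0 with a replicate block, above background on all arrays and without liver samples (1716, 787 and 2830 unadjusted), and 1 to 35 without 1 sample. Within the 6 samples with H2-D1 below the control level limma called 1 (646 unadjusted).

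Lists called, 19, 13 and 12 as reported for lethal minus control, sublethal minus control and lethal minus sublethal, were 9, 8 and 6 above background on all arrays and 0, 0 and 0 with an estimated correlation. For sublethal minus control they were 4 as deposited, 1 with H2-D1 as a term, 2 within its control level, 0 with fry and 6 to 14 without 1 sample. For lethal minus sublethal they were 1 with fry and 8 to 17 without 1 sample. For lethal minus control they were 15 with fry.

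For lists, the values are the mean of the members minus that of the other genes. Direction reversed, lethal minus control, within H2-D1 at the control level for T cells (0.0457), oxidative phosphorylation (-0.0383) and H2-Q6 (0.24), with H2-D1 as a term for oxidative phosphorylation (-0.0414), and above background on all arrays for cell cycle (-0.0599). On the filter for 4 arrays Cd8b1 gave 0.51 and Gp1bb -0.26, and as deposited Fcrla gave 0.12, Ccr7 0.16 and Hemgn 0.0244. For sublethal minus control, within H2-D1 at the control level, mature neutrophils gave -0.0169, monocytes -0.23, platelets -0.0726, interferon gamma -0.0287 and fungal recognition -0.0540. Monocytes gave -0.0337 with H2-D1 as a term, erythroid 0.0819 without liver samples and Nsmce2 0.04004 above background on all arrays. For lethal minus sublethal, T cells gave 0.0211 and erythroid 0.0155 as deposited, T cells 0.47 within H2-D1 at the control level, and platelets -0.0129 below that level and -0.0351 without liver samples.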

Other observations

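Of the 11 lists without a call between lethal and control blood, natural killer genes stood apart in a single sample: their score was 0.70 in lethal replicate 1 and between -0.35 and 0.16 in the other 4 (1 of 20 members rose, 0 fell; camera adjusted p = 0.322). Class II genes scored -0.51 ± 0.26 (SD, n = 5), below all controls in 5 of 5 lethal samples, with -0.89 in lethal replicate 3. Iron and heme genes had 3 of 24 up and 4 down, a median of -0.07 and a mean of 0.32, which differ in sign (adjusted p = 0.945). Apoptosis genes had 4 of 24 up and 3 down (adjusted p = 0.262), and plasma cell genes 2 of 11 up and 2 down (0.49). In the lists for eosinophils and mast cells 1 of 13 rose and 1 fell (0.192), for dendritic cells 1 of 15 rose (0.956), for interleukin 17 1 of 13 rose (0.264) and for ribosomal proteins 1 of 30 rose (0.745). Among 5 globin genes, whose RNA was depleted, 0 rose and 0 fell in limma (adjusted p = 0.641 for the list).

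Cell cycle genes scored 0.73 and 0.70 in lethal replicates 2 and 3 and 0.53 in sublethal replicate 3, and between -0.13 and 0.09 in the other 10 samples. Platelet genes scored between 0.36 and 1.25 in the lethal samples, above all controls in 5 of 5. In the sublethal samples they scored 0.66, 0.54 and 0.82 in replicates 1, 3 and 4-5 and -0.81 in replicate 2.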
